A study of Mus musculus with 12 samples.

How the data were processed

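The 12 libraries were made from polyadenylated RNA of the entire right kidney, which was kept in Qiazol, homogenised and extracted with a column kit and DNase digestion, per the labels' protocols. Libraries were built with the TruSeq RNA kit version 2, which does not mark strand. Reads were aligned with HISAT2 to the mouse genome build mm10, per the submitters' processing notes. The HISAT2 version, the counting program, the annotation it used and its treatment of reads that match several places are not given in the sources used here. The authors deposited 1 table of raw counts per gene, with whole numbers for each library and the total exon width of each gene, and its values were not normalized. Each column was assigned to its library by the identifier in the sample titles. No gene lacked a name and 0 columns belonged to samples outside the series.

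Groups were taken from the genotype label: wildtype (n = 5), Myc (n = 3) and Grhl2KO_Myc (n = 4). Replicates of a group were compared before averaging, and the most similar pair differed by a chi-square of 12.7 per degree of freedom, above sampling noise, so each library was counted as 1 replicate. Total counts lay between 52973520 and 108164810 per library. The table lists 46403 genes, of which 90.6% matched a symbol in the GENCODE M21 annotation of mm10. Coordinates, strands and gene types were taken from that annotation, which may differ from the one the authors counted with.

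Differential expression was tested on the deposited counts with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the default expression filter of edgeR and a quasi-likelihood F test. All 12 libraries entered 1 fit with a coefficient per group and no other covariate. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, and 23742 genes passed the filter. Standard errors were derived from the log2 fold change and its test statistic. The tests of genes and of lists, the gene lists and the rule for naming genes were fixed before the data were examined. Grhl2, Grhl1, Grhl3 and Myc were named always. For each comparison the rule for other names took, among called genes with at least 1 CPM on average in either group and no overlap between the libraries of the groups, the 10 with the largest rise and the 10 with the largest fall. It left out numbered gene models, pseudogenes, immunoglobulin and T cell receptor segments, Y-linked genes, Xist and Tsix. For each gene list up to 4 members with the smallest adjusted p were named, and Cdh1, Epcam, Cldn4, Aqp2, Foxi1, Pkd1, Pkd2, Pkhd1, Havcr1 and Lcn2 whatever their p.

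The 36 gene lists cover Grhl2-linked epithelial genes, cell types of the kidney and of tissue next to it, growth and energy metabolism, inflammation, stress, cystic disease, kidney development and sex-biased expression. The Y-linked list served only to look for a difference in sex. Lists were tested with camera from limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 36 lists of a comparison. Camera with a correlation estimated from the data and fry were run beside it. With the preset correlation 14, 12 and 20 lists passed for Myc against wildtype, Grhl2KO_Myc against wildtype and Grhl2KO_Myc against Myc, and 0 passed in each with an estimated correlation. Fry, which asks whether the genes of a list move to 1 side on balance, called 1, 7 and 5. Between Myc and wildtype this was the Grhl2-linked epithelial list. Between Grhl2KO_Myc and wildtype they were principal cells, the distal convoluted tubule, podocytes, endothelium, ribosome biogenesis, MYC-linked metabolism and epithelial-mesenchymal transition. Between Grhl2KO_Myc and Myc they were Grhl2-linked epithelial genes, principal cells, intercalated cells, ribosome biogenesis and MYC-linked metabolism. A list score is the mean log2 CPM of its measured genes relative to the mean over the 12 libraries.

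The test was run first on simulated counts drawn from the means and library sizes of the real data. The changed genes were picked among those above 1 CPM on average, and list genes at a higher level. Recovery of less expressed genes was therefore not measured. For Myc against wildtype it recovered 55.2%, 80.6% and 100% of the genes changed 1.5-fold, 2-fold and 4-fold with 6 false calls, for Grhl2KO_Myc against wildtype 56.7%, 91.0% and 98.5% with 8 and for Grhl2KO_Myc against Myc 56.7%, 91.0% and 97.0% with 8, over 23742 genes. A simulated list of 30 genes shifted by 0.3 on the log2 scale was called in each comparison and 0 of 9 other lists were. Each gene was drawn independently there, so this does not show how often lists of correlated genes are called without a change. Shares of counts carry 95% Wilson intervals, and correlations across libraries were tested with 100000 random permutations.

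Alternatives were RLE and upper-quartile scaling, no filter beyond 1 count, a filter of 1 CPM in 3 libraries, DESeq2 1.42.0, limma-voom, a fit of only the groups compared, a term for sex read from Y-linked counts, a block on the replicate number, a test against a fold of 1.5, and leaving out each library in turn. Fits without wildtype 4, Grhl2KO_Myc 3 and Grhl2KO_Myc 4 together, with the proximal tubule score as a covariate, and on libraries 1 to 3 without the block were chosen after the data were seen, and so were the sex term and the single libraries left out for the correlation of both comparisons with wildtype. Counts of the called members of each list with single libraries left out were also added then. All 12 libraries were simulated gene by gene without change between groups, to judge how far the comparisons with wildtype resemble each other. Sequences of the called genes in 1 interval of chromosome 4, chosen after the results were seen, were compared with blastn 2.17.0+. The total exon width in the table was not used, and a Grhl2 knockout without Myc overexpression was not analysed here.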

Results

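Polyadenylated RNA from the entire right kidney of mice was sequenced in 12 libraries of 3 genotypes. Wildtype mice (n = 5), as the labels define them, carried a floxed Grhl2 gene on both chromosomes and a MYC transgene at the Rosa26 locus that stays silent until Cre recombinase removes a stop cassette. Kidneys labelled as Myc overexpression (n = 3) form the Myc group, whose cross and Grhl2 genotype are not given in the sources used here, although the library identifiers hold the letters HET. Kidneys labelled as Grhl2 knockout with Myc overexpression (n = 4) form the Grhl2KO_Myc group, bred with HoxB7-Cre, which is active in the ureteric bud and the collecting duct that grows from it. Grhl2 encodes a transcription factor of epithelial cells, and the title of the series asks how it bears on the growth of renal cysts in a mouse model. Total counts assigned to genes lay between 52973520 and 98713157 in the wildtype libraries. They lay between 70608817 and 101043826 in the Myc libraries and between 75187006 and 108164810 in the Grhl2KO_Myc libraries. After removal of genes with few counts, 23742 genes were tested in each comparison. Levels are given as CPM, counts relative to the library total after scaling with TMM factors, as mean ± SD over the libraries of a group, and fold changes are on the log2 scale with their standard error (SE). The labels do not say that the libraries of a group came from separate mice, so the p-values measure only the spread between these samples. No group with the knockout alone was analysed here, and the age of the mice is not given in the sources used here.

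Grhl2 (ENSMUSG00000022286.16, chromosome 15, 37233036 to 37363569, plus strand, mm10) was measured at 29.3, 24.9, 25.6, 24.0 and 25.2 CPM in wildtype libraries 1 to 5. It was measured at 28.5, 33.1 and 28.2 CPM in Myc libraries 1 to 3, and at 18.5, 19, 24.3 and 22.3 CPM in Grhl2KO_Myc libraries 1 to 4. Grhl2 was 1.42-fold lower in Grhl2KO_Myc (21.0 ± 2.78 CPM, n = 4) than in Myc (29.9 ± 2.71 CPM, n = 3), a log2 fold change of -0.51 (SE 0.10, edgeR adjusted p = 0.044), with every Grhl2KO_Myc library below every Myc library. Leaving out Myc 1, Myc 2 or Myc 3 raised that adjusted p to 0.13, 0.21 and 0.077, and leaving out Grhl2KO_Myc 1, 2 or 4 raised it to 0.090, 0.11 and 0.091. Against wildtype (25.8 ± 2.04 CPM, n = 5) the log2 fold change of Grhl2 was -0.29 (SE 0.092, adjusted p = 0.082), which passed the threshold without wildtype 4 (adjusted p = 0.044) or without Grhl2KO_Myc 3 (0.049). The whole kidney holds many cells in which HoxB7-Cre is not active, the exons that recombination removes are not given in the sources used here, and the kit does not separate Grhl2 from the antisense models Gm16136 and Gm16137 annotated over it. The related gene Grhl3 rose 2.10-fold in Grhl2KO_Myc over wildtype (6.43 ± 2.03 against 3.06 ± 0.69 CPM, log2 fold change 1.07, SE 0.22, adjusted p = 0.013), and Grhl1 was at 7.18 ± 1.16 against 6.30 ± 0.839 CPM (adjusted p = 0.39). Transcripts counted at the mouse Myc gene were at 26.7 ± 6.06 CPM in wildtype, 23.6 ± 4.24 CPM in Myc and 30.1 ± 2.23 CPM in Grhl2KO_Myc, with log2 fold changes over wildtype of -0.18 (SE 0.17, adjusted p = 1) and 0.17 (SE 0.15, adjusted p = 0.55), and whether transgene reads are counted at that gene is not given in the sources used here.

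Libraries also differed within groups. The 30 proximal tubule markers, of which 29 were measured, had a mean score (log2 CPM relative to the mean over libraries) of -1.35 in wildtype 4, -1.04 in Grhl2KO_Myc 3 and -0.90 in Grhl2KO_Myc 4, against -0.16 to 0.73 in the other 9 libraries. Those 3 libraries also lay apart on the first principal component, which held 21.2% of the variance, at 46.1, 34.4 and 42.1, where no other library was above 16.0. Y-linked Ddx3y was at 62.8 to 81.2 CPM in wildtype 5, Myc 3, Grhl2KO_Myc 1 and Grhl2KO_Myc 4 and at no more than 1.33 CPM in the other 8 libraries. Xist was at 871 to 1010 CPM in 7 of those 8 libraries and at 0.213 CPM in Grhl2KO_Myc 3, where the Y-linked genes Ddx3y and Eif2s3y were at 0 CPM and Kdm5d at 4.87 CPM, as in the other libraries without Ddx3y (3.72 to 5.96 CPM). Yam1, Rn18s-rs5 and Lars2, genes at which reads of ribosomal RNA are often counted, together took 5.55% of the counts in Myc 1 (95% Wilson interval 5.545 to 5.554), against 0.16% to 0.581% in the others. That interval covers counting error only.

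**Figure D1:**
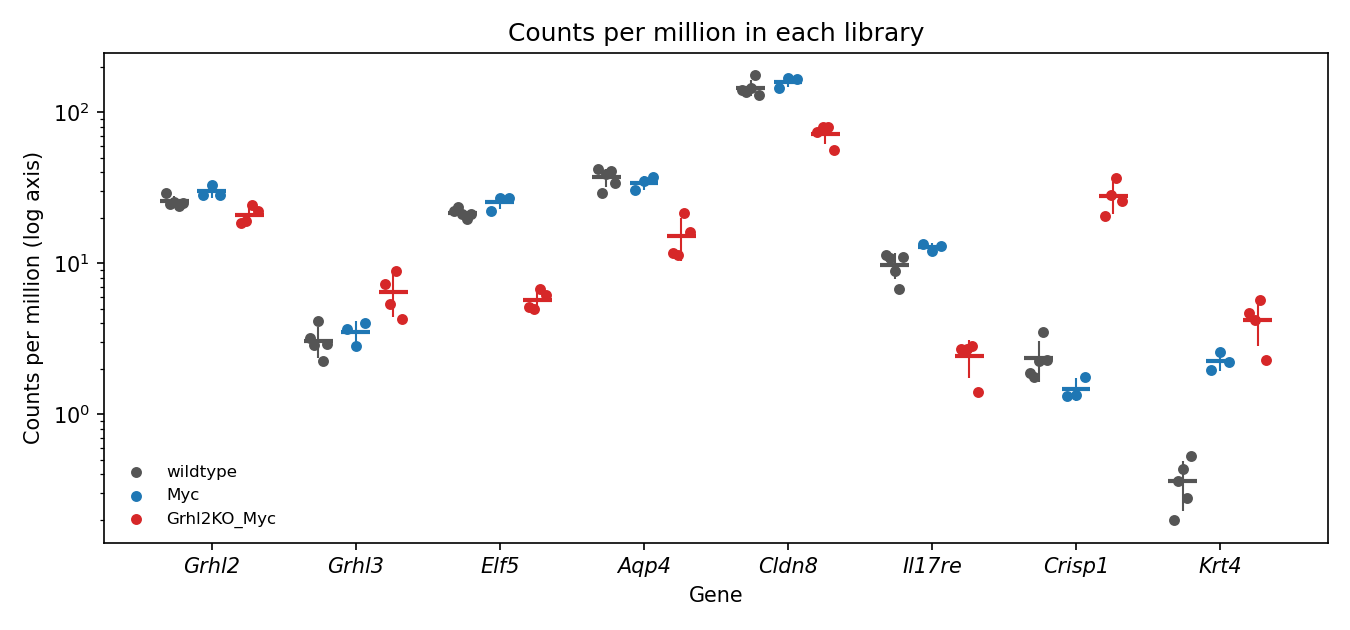
CPM of 8 genes on a log axis in each library, by genotype group; points are libraries, the bar is the group mean and the vertical line its SD. Crisp1 lies at 28.0 ± 6.78 CPM in Grhl2KO_Myc against 2.34 ± 0.703 CPM in wildtype, Elf5 at 5.75 ± 0.85 against 21.5 ± 1.41 CPM, and Grhl2 at 21.0 ± 2.78 against 25.8 ± 2.04 CPM.

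Myc kidneys were compared with wildtype kidneys, from which they differ on the labels by Myc overexpression. The keratin gene Krt4 (chromosome 15, 101918535 to 101924735, minus strand) rose 6.26-fold, from 0.359 ± 0.130 CPM in wildtype (n = 5) to 2.25 ± 0.309 CPM in Myc (n = 3), and was the only gene called (log2 fold change 2.65, SE 0.30, adjusted p = 0.030). Foxi1, the transcription factor of intercalated cells, was at 41.7 ± 13 against 22.9 ± 1.97 CPM (log2 fold change 0.87, SE 0.16, adjusted p = 0.31). Among the 20 intercalated cell markers 0 passed over all genes and 7 were higher when adjusted over the list alone, among them the proton pump subunit genes Atp6v1g3 (0.67, SE 0.15, adjusted p = 0.48 over all genes) and Atp6v1c2 (0.53, SE 0.11, adjusted p = 0.48). As a set they lay above the other genes (median 0.34, from 0.19 without wildtype 4 to 0.40 without wildtype 5, camera adjusted p = 2.1e-09), with adjusted p = 0.23 with an estimated correlation. The 30 Grhl2-linked epithelial genes had a median of 0.11 with 27 above 0 and 5 higher when adjusted over the list alone (camera adjusted p = 1.3e-07, adjusted p = 0.14 with an estimated correlation), among them Rab25, a small GTPase of epithelial vesicle traffic, at 0.52 (SE 0.093, adjusted p = 0.28 over all genes). Every one of the 32 ribosome biogenesis genes was above 0, with a median of 0.12, 0 called over all genes and 0 when adjusted over the list alone (camera adjusted p = 1.3e-09, adjusted p = 0.46 with an estimated correlation). The 20 endothelial markers were all below 0 with a median of -0.15 (-0.18 to -0.10 with single libraries left out) and 0 called either way (camera adjusted p = 2.1e-09, adjusted p = 0.23 with an estimated correlation). The 24 measured interferon-induced genes were all below 0 with a median of -0.36 and 0 called either way (camera adjusted p = 8.4e-06, adjusted p = 0.56 with an estimated correlation). That median lay between -0.50 without Myc 1 and -0.24 without wildtype 4.

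With 1 call by edgeR, 1098 genes had an unadjusted p under 0.05 where 1187 would by chance, DESeq2 called 43 genes (38 higher and 5 lower) and limma-voom called 0. Genes whose Myc libraries all lay on 1 side of every wildtype library numbered 847, or 3.57%, and chance gives 3.57%. The call of Krt4 was lost without wildtype 1 (adjusted p = 0.091), wildtype 2 (0.18), wildtype 3 (0.11), wildtype 4 (0.13), Myc 2 (0.25) or Myc 3 (0.18), each of which left 0 genes called, and 6 genes were called without Myc 1, the library rich in ribosomal RNA counts.

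Grhl2KO_Myc kidneys were compared with wildtype kidneys, from which they differ on the labels by the knockout and the overexpression. Elf5 (chromosome 2, 103411688 to 103450989, plus strand), an ETS transcription factor gene of collecting duct principal cells, was 3.74-fold lower (5.75 ± 0.85 against 21.5 ± 1.41 CPM, n = 4 and 5, log2 fold change -1.90, SE 0.10, adjusted p = 3.5e-06). The water channel gene Aqp4 (chromosome 18, 15389496 to 15410982, minus strand) of the same cells was 2.44-fold lower (15.2 ± 4.78 against 37.1 ± 5.33 CPM, adjusted p = 0.0016). Avpr2, the vasopressin receptor of the collecting duct, was 1.91-fold lower (adjusted p = 0.00029). Crisp1 (chromosome 17, 40293758 to 40319207, minus strand), which encodes a secreted protein known from the epididymis, rose 12-fold to 28.0 ± 6.78 CPM from 2.34 ± 0.703 CPM (log2 fold change 3.58, SE 0.22, adjusted p = 7.9e-06). Genes that serve the making of ribosomes rose together by small amounts, 27 of 32 of them, with a median log2 fold change of 0.38 (adjusted p = 0.18 for the list with an estimated correlation).

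Of the 23742 genes 1584 passed the test, 965 higher and 619 lower, and 127 of the higher and 80 of the lower differed by at least 2-fold. The 10 largest rises that met the naming rule were Disp2, Ugt2b35, Crisp1, Krt4, Kcnj3, Fgf15, AI118078, Aqp5, Vsig1 and Gng4, from 4.33 to 2.14 on the log2 scale, of which Vsig1 lost its call without Grhl2KO_Myc 3 (adjusted p = 0.058) or Grhl2KO_Myc 4 (0.060). Krt4 rose 11.8-fold (4.23 ± 1.42 against 0.359 ± 0.130 CPM, adjusted p = 6.1e-05), and Aqp5, a water channel gene of secretory epithelia, rose 4.96-fold (4.96 ± 0.891 against 1.00 ± 0.206 CPM, adjusted p = 0.00015). Kcnj3, which encodes a potassium channel subunit, rose 11.6-fold to 1.06 ± 0.382 CPM (adjusted p = 0.00028), and Fgf15, a hormone gene of the intestine, rose 6.67-fold to 2.96 ± 1.18 CPM (adjusted p = 0.00068). Disp2 rose 20.2-fold, to 1.67 ± 1.86 CPM, with an SD above its mean. The 10 largest falls were Gsdmc3, Bglap3, Ces1d, Myo3b, Il17re, Elf5, Wfdc15b, Aqp6, Apoc1 and Macc1, from -2.39 to -1.62. Il17re (chromosome 6, 113458484 to 113470758, plus strand), a receptor gene of the interleukin-17 family, was 4.07-fold lower (2.41 ± 0.674 against 9.78 ± 1.94 CPM, adjusted p = 0.00024), and Wfdc15b was 3.18-fold lower (7.09 ± 1.96 against 22.5 ± 1.79 CPM, adjusted p = 0.00015). Values of Gsdmc3, Ugt2b35 and Ces1d are uncertain, since each belongs to a family of similar genes between which reads can be shared. Genes with every Grhl2KO_Myc library on 1 side of every wildtype library numbered 2249, or 9.47%, where chance gives 1.59%. The count of 1584 was 3778 without wildtype 4, 935 without wildtype 1, 894 without wildtype 2, 885 without wildtype 3, 1046 without Grhl2KO_Myc 1, 832 without Grhl2KO_Myc 3 and 750 without Grhl2KO_Myc 4. DESeq2 called 2703 genes, the count was 998 with a term for sex and 2431 with the proximal tubule score as a covariate, and 75 genes passed a test against a fold of 1.5.

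Among the 20 principal cell markers 5 fell (3 to 8 with single libraries left out) and 0 rose over all genes, with 7 lower and 4 higher when adjusted over the list alone (median -0.18, from -0.24 without wildtype 5 to 0 without wildtype 4), and Aqp2 itself was at 328 ± 54.0 against 370 ± 123 CPM (adjusted p = 0.70). The list as a set missed the threshold by camera (adjusted p = 0.071, adjusted p = 0.41 with an estimated correlation), while fry called it (adjusted p = 0.0012). Of the 20 intercalated cell markers 2 fell (2 to 7 with single libraries left out) and 1 rose (0 to 2), with 2 lower and 3 higher when adjusted over the list alone. Their median was -0.21, and -0.33 to -0.14 with single libraries left out (camera adjusted p = 0.27, adjusted p = 0.82 with an estimated correlation). Aqp6, a channel of these cells, was 3.10-fold lower (2.11 ± 0.386 against 6.55 ± 1.93 CPM, adjusted p = 0.0014), and the Notch ligand gene Jag1 was 1.32-fold lower (105 ± 6.30 against 138 ± 10.1 CPM, adjusted p = 0.0052). Foxi1 rose 1.56-fold (35.6 ± 4.94 against 22.9 ± 1.97 CPM, adjusted p = 0.026), a call lost without wildtype 1 (0.051), wildtype 3 (0.064), Grhl2KO_Myc 1 (0.061), Grhl2KO_Myc 3 (0.082) or Grhl2KO_Myc 4 (0.063). The 30 Grhl2-linked epithelial genes moved both ways, with 6 lower (4 to 9 with single libraries left out) and 3 higher (3 to 5) over all genes and 9 lower and 4 higher when adjusted over the list alone. Their median was -0.06, and -0.13 to -0.03 with single libraries left out (camera adjusted p = 0.14). The tight junction gene Cldn8 (chromosome 16, 88560828 to 88563183, minus strand) was 2.02-fold lower (72.4 ± 10.9 against 146 ± 17.7 CPM, adjusted p = 0.00037) and Arhgef19 was 2.05-fold lower (10.4 ± 0.779 against 21.4 ± 3.20 CPM, adjusted p = 0.00037). The epithelial transcription factor gene Ehf rose 1.69-fold (72.0 ± 6.37 against 42.7 ± 2.38 CPM, adjusted p = 0.00031). Epcam was 1.21-fold lower (171 ± 2.07 against 207 ± 13.5 CPM, adjusted p = 0.0097), while Cdh1 (225 ± 12.1 against 225 ± 8.81 CPM, adjusted p = 0.99) and Cldn4 (55.1 ± 6.16 against 54.7 ± 4.36 CPM, adjusted p = 0.97) did not pass.

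Of the 32 ribosome biogenesis genes 27 rose (21 to 31 with single libraries left out) and 0 fell over all genes, and all 32 were higher when adjusted over the list alone (camera adjusted p = 1.8e-26, adjusted p = 0.18 with an estimated correlation). Examples are Ddx21, an RNA helicase gene of the nucleolus (119 ± 8.75 against 87.0 ± 2.03 CPM, log2 fold change 0.45, SE 0.052, adjusted p = 0.00052), Nop58 (0.35, SE 0.042, adjusted p = 0.00068) and Bop1 (0.52, SE 0.065, adjusted p = 0.00083). Of the 28 genes of growth metabolism and translation often described as MYC targets 21 rose (11 to 21 with single libraries left out) and 0 fell, with 23 higher when adjusted over the list alone. Their median was 0.32 (camera adjusted p = 2.1e-17, adjusted p = 0.18 with an estimated correlation). They included Impdh2 of guanine nucleotide synthesis (145 ± 6.39 against 102 ± 2.63 CPM, adjusted p = 9.9e-05), Gart of purine synthesis (102 ± 10.9 against 69.6 ± 2.22 CPM, adjusted p = 0.00074) and the amino acid transporter gene Slc7a5 (48.5 ± 4.63 against 31.2 ± 2.92 CPM, adjusted p = 8.0e-04). Of 30 cell cycle genes 0 rose and 1 fell (0 to 3 with single libraries left out), also when adjusted over the list alone. Their median was -0.13, and -0.22 to -0.02 with single libraries left out (camera adjusted p = 0.31). The proximal tubule scores of the same libraries were low in Grhl2KO_Myc 3 and 4 (-1.04 and -0.90) and in wildtype 4 (-1.35), and the ribosome biogenesis score was -0.01 in wildtype 4 against -0.21 to -0.17 in the other wildtype libraries and 0.15 to 0.33 in Grhl2KO_Myc.

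Markers of other kidney cells were also compared between Grhl2KO_Myc and wildtype. Of 20 podocyte markers 5 fell (2 to 9 with single libraries left out) and 0 rose, with 9 lower when adjusted over the list alone. Their median was -0.25 (camera adjusted p = 1e-06, adjusted p = 0.18 with an estimated correlation). Podxl was among the lower genes (315 ± 13.5 against 420 ± 23.4 CPM, adjusted p = 0.0037). Of 20 endothelial markers 4 fell (1 to 6 with single libraries left out), with 7 lower when adjusted over the list alone. Their median was -0.15 (camera adjusted p = 2.3e-05, adjusted p = 0.41 with an estimated correlation). The receptor gene Tek was among the lower genes (62.9 ± 3.84 against 77.6 ± 4.62 CPM, adjusted p = 0.0081). The calls of Kdr, Flt1 and Plat were lost without Grhl2KO_Myc 3 (0.054, 0.064 and 0.083). The 17 markers of the distal convoluted tubule had 2 lower (1 to 6 with single libraries left out) and 1 higher (1 to 2) over all genes, and 10 lower and 2 higher when adjusted over the list alone. Their median was -0.41 (camera adjusted p = 0.0030, adjusted p = 0.41 with an estimated correlation). Klhl3 was 1.71-fold lower (5.43 ± 0.576 against 9.29 ± 1.46 CPM, adjusted p = 0.0066) and Ppp1r1b was 1.68-fold higher (8.76 ± 1.03 against 5.21 ± 0.993 CPM, adjusted p = 0.0092). The 18 markers of the thick ascending limb had 1 higher (1 in each fit with a library left out) and 1 lower (1 to 8) over all genes and 1 higher and 8 lower when adjusted over the list alone. Their median was -0.26 (camera adjusted p = 0.0027, adjusted p = 0.43 with an estimated correlation). None of the 29 measured proximal tubule markers passed over all genes or over the list alone, with 27 of 29 below 0 and a median of -0.51 (camera adjusted p = 0.014, adjusted p = 0.82 with an estimated correlation). That median lay between -0.84 without Grhl2KO_Myc 1 and -0.32 without Grhl2KO_Myc 3, and camera called the list in 4 of 9 fits with a library left out. Of 25 genes mutated in inherited cystic kidney disease 4 fell (0 to 8 with single libraries left out) and 0 rose, with 7 lower when adjusted over the list alone. Their median was -0.09 (camera adjusted p = 0.0043, adjusted p = 0.59 with an estimated correlation). Pkd2 was 1.19-fold lower (143 ± 6.83 against 170 ± 13.9 CPM, adjusted p = 0.032), a call lost without wildtype 1 (0.072), wildtype 2 (0.066), wildtype 3 (0.072), wildtype 5 (0.061), Grhl2KO_Myc 2 (0.051), Grhl2KO_Myc 3 (0.093) or Grhl2KO_Myc 4 (0.098). The calls of Glis2, Kif3a and Glis3 were also lost without wildtype 1 (0.051, 0.084 and 0.10). Pkd1 was at 96.7 ± 5.76 against 103 ± 9.11 CPM (adjusted p = 0.43) and Pkhd1 at 42.7 ± 6.17 against 60.7 ± 19.1 CPM (adjusted p = 0.21). The injury markers Havcr1 (0.720 ± 0.0797 against 0.559 ± 0.241 CPM, adjusted p = 0.52) and Lcn2 (11.7 ± 1.71 against 11.3 ± 1.47 CPM, adjusted p = 0.84) did not pass. Of the 25 genes raised in injured tubules 1 rose (1 to 2 with single libraries left out) and 1 fell (0 to 2), also when adjusted over the list alone. Their median was 0.05, but -0.14 without Grhl2KO_Myc 2 (camera adjusted p = 0.99). The gene that rose there was Krt19, at 50.2 ± 12.9 against 26.4 ± 5.41 CPM (adjusted p = 0.011).

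**Figure D2:**
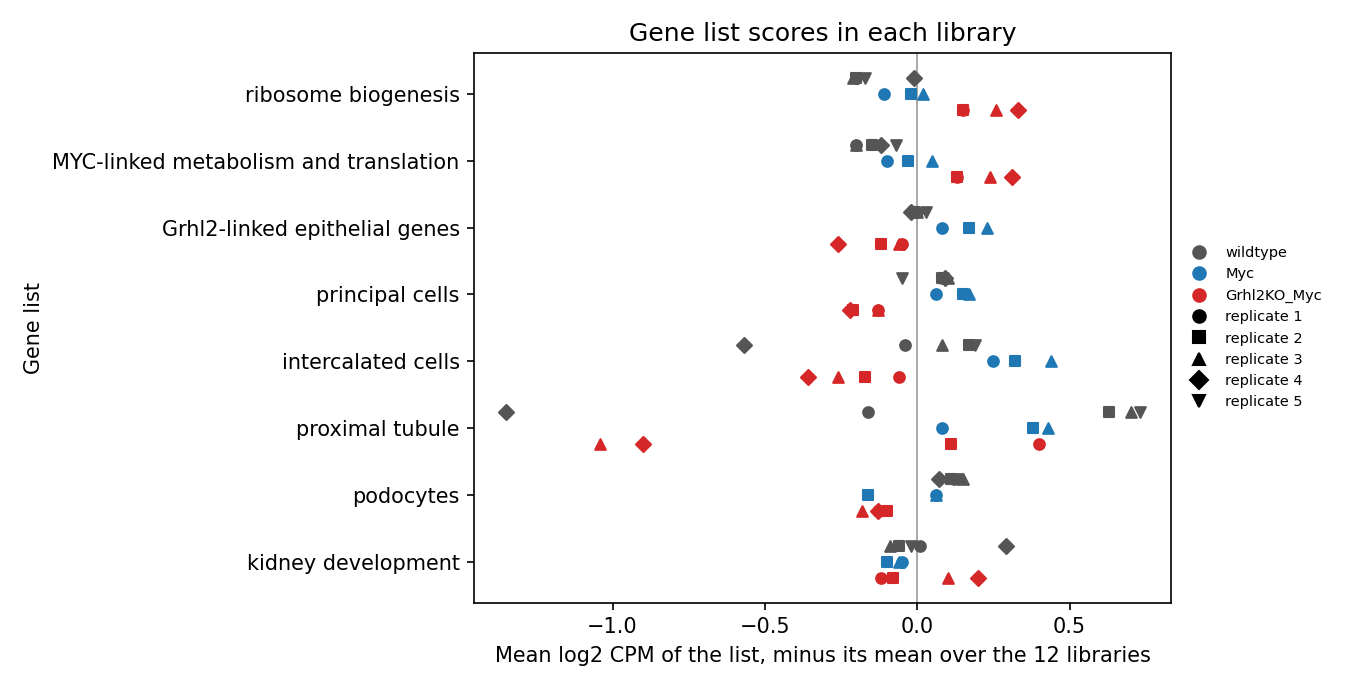
Scores of 8 gene lists in each of the 12 libraries, as mean log2 CPM of the list relative to the mean over libraries; colour marks the genotype group and marker shape the replicate number. The ribosome biogenesis score lies between 0.15 and 0.33 in the Grhl2KO_Myc libraries and between -0.21 and -0.01 in wildtype, and the proximal tubule score is -1.35 in wildtype 4.

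Grhl2KO_Myc kidneys were compared with Myc kidneys, which on the labels differ by the knockout of Grhl2. Elf5 was 4.42-fold lower (5.75 ± 0.85 CPM, n = 4, against 25.4 ± 2.68 CPM, n = 3, log2 fold change -2.14, SE 0.11, adjusted p = 4.5e-06), Cldn8 2.21-fold lower (72.4 ± 10.9 against 160 ± 13.1 CPM, adjusted p = 0.00084) and Avpr2 2.00-fold lower (7.45 ± 1.30 against 14.9 ± 0.228 CPM, adjusted p = 9.0e-04). Crisp1 was 18.8-fold higher (28.0 ± 6.78 against 1.48 ± 0.254 CPM, log2 fold change 4.24, SE 0.28, adjusted p = 2.9e-05). Asic4, a gene of the acid-sensing ion channel family, was 4.01-fold higher (3.51 ± 0.549 against 0.874 ± 0.133 CPM, adjusted p = 0.00026). Il17re was 5.35-fold lower (2.41 ± 0.674 against 12.9 ± 0.671 CPM, adjusted p = 0.00029) and Macc1 5.01-fold lower (0.903 ± 0.359 against 4.51 ± 0.521 CPM, adjusted p = 0.0010).

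In this comparison 200 genes passed, 85 higher and 115 lower, of which 33 and 53 differed by at least 2-fold. Of these, 83 of the 85 higher and 104 of the 115 lower genes also passed in the same direction against wildtype. Both comparisons use the same Grhl2KO_Myc libraries, so their calls are not independent. Among the largest rises by the naming rule were Crisp1, Ugt2b35, Kcnj3, Fgf15, Spock1, Ppp2r2c, Asic4, Vwa5b1 and Npy6r, from 4.24 to 1.63, and the largest falls were Gsdmc3, Gsdmc4, Gsdmc2, Gsdmc, Rbbp8nl, Ces1d, Myo3b, Il17re, Macc1 and Bglap3, from -3.51 to -2.19. Crisp1, Asic4, Gsdmc3, Myo3b, Il17re, Macc1 and Bglap3 passed whichever single library was left out. The other 12 of these 19 genes each lost the call without at least 1 library, Myc 2 or Myc 3 among them in every case, with adjusted p between 0.051 (Fgf15 without Myc 2) and 0.18 (Spock1 without Myc 1). The 4 Gsdmc genes, which encode gasdermins that form membrane pores, lie side by side on chromosome 15 between 63775968 and 63912297 (mm10) and resemble each other in sequence, so their counts are not independent measurements. Gsdmc3 was at 2.35 ± 1.06 CPM in Grhl2KO_Myc, 26.5 ± 13 CPM in Myc and 12.2 ± 4.73 CPM in wildtype. Genes with every Grhl2KO_Myc library on 1 side of every Myc library numbered 3999, or 16.8%, where chance gives 5.71%. The count of 200 was 78 without Myc 1, 70 without Myc 2, 88 without Myc 3, 123 without Grhl2KO_Myc 2, 111 without Grhl2KO_Myc 3 and 91 without Grhl2KO_Myc 4, while DESeq2 called 784. Without wildtype 4, Grhl2KO_Myc 3 and Grhl2KO_Myc 4, the libraries lowest in proximal tubule markers, 318 genes were called, and 38 passed a test against a fold of 1.5.

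Of the 30 Grhl2-linked epithelial genes 4 fell (4 in each fit with a library left out) and 0 rose, with 12 lower and 3 higher when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 7.9e-06, adjusted p = 0.19 with an estimated correlation). Those that fell were Arhgef19 (2.50-fold lower, 10.4 ± 0.779 against 26.1 ± 2.91 CPM, adjusted p = 0.00029), Cldn8, Rab25 (1.83-fold lower, 8.48 ± 0.642 against 15.5 ± 1.80 CPM, adjusted p = 0.0010) and the junction gene Cgn (1.38-fold lower, 41.9 ± 1.83 against 57.9 ± 2.77 CPM, adjusted p = 0.0026). Epcam was at 171 ± 2.07 against 208 ± 10.1 CPM (adjusted p = 0.051). Of the 20 principal cell markers 4 fell (2 to 5 with single libraries left out) and 0 rose, with 7 lower and 1 higher when adjusted over the list alone. Their median was -0.20 (camera adjusted p = 0.0018, adjusted p = 0.19 with an estimated correlation). Aqp4, 1 of these 4, was 2.26-fold lower (adjusted p = 0.017), a call lost without Myc 2 (0.080), Myc 3 (0.068) or Grhl2KO_Myc 4 (0.053). Of the 20 intercalated cell markers 3 fell (1 to 3 with single libraries left out) and 0 rose, with 10 lower when adjusted over the list alone. Their median was -0.48 (camera adjusted p = 1.3e-08, adjusted p = 0.24 with an estimated correlation). Aqp6 was among the lower genes (3.98-fold lower, 2.11 ± 0.386 against 8.40 ± 0.374 CPM, adjusted p = 0.0018). Atp6v0d2 lost its call whichever single library was left out (adjusted p from 0.068 to 0.21). Atp6v1c2 lost it in each of these fits except that without Grhl2KO_Myc 3 (0.060 to 0.19). The proximal tubule list, with 0 of 29 called either way, had a median of -0.56 (-0.84 to -0.40 with single libraries left out, camera adjusted p = 0.0011, adjusted p = 0.70 with an estimated correlation). Of the 32 ribosome biogenesis genes 3 rose (0 to 2 with single libraries left out) and 0 fell, with 26 higher when adjusted over the list alone. Their median was 0.26 (camera adjusted p = 2.6e-20, adjusted p = 0.24 with an estimated correlation). Ddx21 was 1.25-fold higher (119 ± 8.75 against 95.5 ± 5.04 CPM, adjusted p = 0.029), a call lost without Myc 1 (0.15), Myc 2 (0.12), Myc 3 (0.060), Grhl2KO_Myc 3 (0.087) or Grhl2KO_Myc 4 (0.073). Of the 28 MYC-linked metabolism and translation genes 2 rose (0 to 2 with single libraries left out) and 0 fell, with 17 higher when adjusted over the list alone. Their median was 0.24 (camera adjusted p = 3.3e-11, adjusted p = 0.28 with an estimated correlation). The genes that rose, Impdh2 and Slc7a5, both lost the call without Myc 1 (0.12 and 0.23), Myc 3 (0.072 and 0.090), Grhl2KO_Myc 3 (0.064 and 0.12) or Grhl2KO_Myc 4 (0.063 and 0.13). Of the 25 genes of inherited cystic disease 0 passed over all genes and 2 were lower when adjusted over the list alone. Their median was -0.08 (camera adjusted p = 0.0018, called in 7 of 7 fits with a library left out, adjusted p = 0.50 with an estimated correlation).

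A stretch of chromosome 4 from 41809083 to 42589938 (mm10), chosen after its values were seen, held 28 tested genes, of which 13 were lower in Grhl2KO_Myc than in Myc and in wildtype. They are gene models and pseudogenes without assigned names, with a median log2 fold change of -1.74 against Myc and -1.83 against wildtype, and their sequences resemble each other, so their counts are uncertain. Gm13301 (-3.28, SE 0.26, adjusted p = 0.00016) fell to 0.478 ± 0.114 CPM from 4.63 ± 0.271 CPM in Myc, and Gm10600 (-2.66, SE 0.23, adjusted p = 0.00022) fell to 1.01 ± 0.288 CPM from 6.36 ± 0.539 CPM. The mean log2 CPM of the 13 genes lay between 0.01 and 0.67 in the 4 Grhl2KO_Myc libraries and between 1.86 and 2.51 in the other 8. The other 15 tested genes of the stretch, which did not pass against Myc, had a median of -0.37 (SE 0.21) there. Gm17081, at -2.45 against Myc (adjusted p = 0.084), was lower than in wildtype (-2.39, adjusted p = 0.024).

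**Figure D3:**
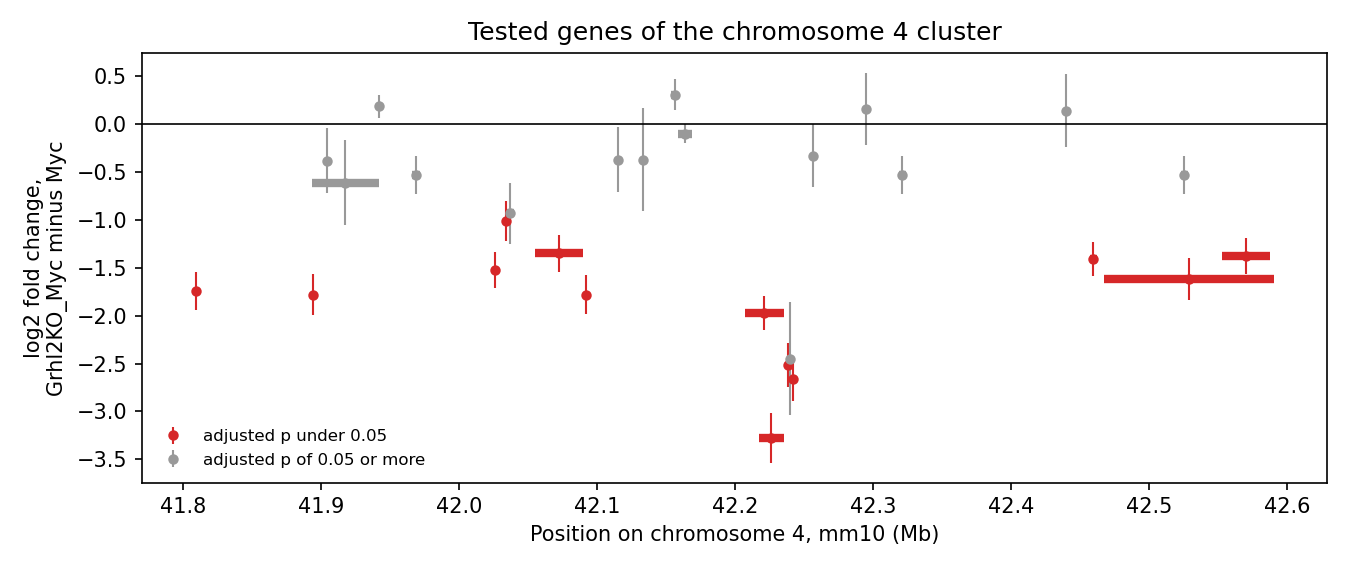
Log2 fold change of Grhl2KO_Myc over Myc for the tested genes between 41809083 and 42589938 on chromosome 4 (mm10), against position; each point is a gene, the error bar its SE, and red points passed the test. The 13 genes that passed have a median of -1.74 and the other 15 a median of -0.37.

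The comparisons of Myc and of Grhl2KO_Myc with wildtype share the wildtype libraries. Across the 23742 genes, which are not independent replicates, the log2 fold changes of both comparisons correlated at r = 0.360 (Spearman 0.377) with a covariance of 0.0504, and 65.2% had the same sign. All 12 libraries were also simulated without any change between groups, with the simulated wildtype libraries shared by both comparisons. They gave a median r of 0.405 (0.383 to 0.446) with a covariance of 0.0329 and 63.6% of the same sign. The observed r lay below that range, while the observed covariance exceeded the simulated value by 0.0175. Genes were drawn independently of each other there, unlike in real libraries, so this excess does not show a shared change. With the wildtype libraries split between the comparisons, over the 20 ways to do so, the median r was 0.006 (-0.073 to 0.167) and the median covariance 0.00107 (-0.0148 to 0.0287). Krt4 was the 1 gene higher in both, and 0 genes were lower in both. Lists drawn independently would share 0.0406 higher genes, but these lists rest on the same wildtype libraries. The simulated libraries gave a median of 0 shared genes in each direction. The correlation was 0.234 without Myc 3.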

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

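Of the tests in this part, those on the proximal tubule pattern were chosen after the result was seen. In wildtype and Grhl2KO_Myc, the library farthest from the rest of its group was tested for the score of each list except the Y-linked one, for each gene always named and for 3 shares or totals of counts, and 14 of 104 groups of values held a library beyond Dixon's critical value, where chance gives about 1 in 20, or 5.2. The values share libraries and genes, so they are not independent and 14 against 5.2 does not measure an excess.

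Wildtype 4 stood apart in most groups of values that held a library beyond the critical value. Its score was -0.22 for the thick ascending limb (others 0.12 to 0.18), -1.80 for adipose tissue (0.55 to 1.29), -1.39 for female-biased kidney genes (0.15 to 0.66) and -0.18 for cystic disease genes (0.07 to 0.11). It was 0.29 for kidney development (-0.09 to 0.01), 0.26 for immediate-early genes (-0.12 to -0.04) and -0.01 for ribosome biogenesis (-0.21 to -0.17). Pkd2 was at 146 CPM in wildtype 4 against 173 to 180 CPM in the other wildtype libraries, and Pkhd1 at 27.4 against 62.8 to 73.1 CPM. Wildtype 5 had a principal cell score of -0.05 where the others lay between 0.08 and 0.10. Grhl2KO_Myc 2 had scores of 2.07 for the adrenal gland (others -0.19 to 0.16), 0.98 for the interferon response (-0.30 to -0.15) and 0.17 for lymphocytes (-0.12 to -0.10), and Epcam at 168 CPM (171 to 172).

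The proximal tubule markers were lower in Grhl2KO_Myc than in wildtype by a median of -0.51, while their score differed by -0.47 between the groups (exact permutation test, p = 0.41 over 126 splits). A lower share of proximal tubule cells in the sample would raise the markers of other cells alike. The median fold change was above 0 for 1 of 9 lists of other cell types. TMM scaling takes out a shift that most genes share, so that rise need not appear, and a lower share stays open. Whether maturity differed between kidneys of 1 group was tested within the groups: over the 12 libraries the deviations from the group means of the proximal tubule and the kidney development scores correlated at r = -0.94 (permutation test, p = 1e-05, the smallest it can give; Spearman coefficient -0.91, p = 0.00011), and at r = -0.89 (permutation p = 3.0e-04) without wildtype 4 and Grhl2KO_Myc 3, the only relation computed in this family. It was -0.85 (permutation p = 0.0070) without Grhl2KO_Myc 4 as well. In both fits the deviations were still taken from group means that include the libraries left out, so both still depend on those libraries. These values bear on the spread within groups and not on the difference between Grhl2KO_Myc and wildtype, where the kidney development score differed by 0 (SE 0.10), so maturity stays open there. Age of the mice, illness of single mice and a part of the kidney missing from a sample stay open and were not tested.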

How the results depend on the processing

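The fits without wildtype 4, Grhl2KO_Myc 3 and Grhl2KO_Myc 4 together, with the proximal tubule score as a covariate, and on libraries 1 to 3 without a block were chosen after seeing the data, as were the sex term and the single libraries left out for the correlation of both comparisons with wildtype. Over all settings 9866 of 10541 values of named genes kept their side of the threshold, 488 lost a call, 187 gained one and 0 reversed. Of 2160 values of lists 1880 kept their side, 171 lost a call, 101 gained one and 8 reversed. Values without a call that stayed without one count as kept, so these totals do not measure how often a call was kept. A reversal here needs a call in either fit and, for lists, another direction by camera. Called or not, 112 of the gene values and 131 of the list medians took the other sign, 0 and 11 of them with a call in either fit.

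For Myc against wildtype the 1 call became 0 with a sex term, against a fold of 1.5, with only the 2 groups and with limma-voom, 43 with DESeq2, and 0 to 6 with single libraries left out. For Grhl2KO_Myc against wildtype the 1584 calls became 998 with a sex term, 75 against a fold of 1.5, 2431 with the proximal tubule covariate, 995 with only the 2 groups, 2703 with DESeq2, and 750 to 3778 with single libraries left out. For Grhl2KO_Myc against Myc the 200 calls became 38 against a fold of 1.5, 318 without the 3 libraries, 304 with the covariate, 784 with DESeq2, and 70 to 163 with single libraries left out. A test against a fold gives fewer calls by construction; for the other changes the cause was not tested. RLE and upper-quartile scaling and both other filters kept these counts within 1.5 times.

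Lists called with the preset correlation numbered 14, 12 and 20, all 0 with an estimated correlation, and 1, 7 and 5 with fry. The correlation of both comparisons with wildtype, 0.360, was 0.006 with the wildtype libraries split and 0.234 to 0.458 with single libraries left out. Medians that took the other sign with a call in either fit were, besides glycolysis below, those of the proximal tubule list for Myc against wildtype (-0.195 without the 3 libraries, and -0.194 without wildtype 4 to 0.133 without wildtype 2), cystic disease genes (-0.034 without the 3 libraries) and fibroblasts (0.010 without Myc 3) in the same comparison, oxidative phosphorylation for Grhl2KO_Myc against Myc (0.011 without the 3 libraries and 0.004 with the covariate) and fatty acid oxidation, at 0.064 without the 3 libraries and 0.033 with the covariate against Myc and 0.136 with the covariate against wildtype. The cause was not tested.

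Replicate numbers recur in the groups, but 1 of 10 pairs of libraries with the same number had correlated deviations above 0.1 (-0.11 to 0.23, median 0.01 against -0.02 for 37 other pairs). These values show no pairing by number, though so few pairs cannot exclude one. With the replicate number as a block on libraries 1 to 3, the calls were 0 for Myc against wildtype, 1087 for Grhl2KO_Myc against wildtype and 98 for Grhl2KO_Myc against Myc, against 1, 1976 and 271 on the same libraries without the block. The median of the glycolysis list for Myc against wildtype became 0.082 with the block, and 0.081 on the same libraries without the block. Depth limits the genes well below 1 CPM, such as Cd3d at 0.0376 ± 0.0204 CPM in Grhl2KO_Myc, which rest on few counts.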

Other observations

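The families, the tests of the ribosome biogenesis pattern, the tests of loss or segregation of the chromosome 4 interval and the counts over other splits of the libraries in this part were chosen after the results were seen. Genes named Snhg are hosts of small nucleolar RNAs, which guide the chemical modification of ribosomal RNA. Of 14 such genes 8 rose and 1 fell in Grhl2KO_Myc against wildtype, and 10 were above 0. Their median log2 fold change was 0.39 (camera with an estimated correlation, p = 0.0066, not adjusted, for a family picked after its values were seen). Snhg4 was 2.34-fold higher (33.4 ± 1.14 against 14.2 ± 0.637 CPM, n = 4 and 5, adjusted p = 1.7e-05) and Snhg12 1.56-fold higher (19.6 ± 3.00 against 12.5 ± 1.60 CPM, adjusted p = 0.0069), with Snhg4 at 22.3 ± 3.71 CPM in Myc (adjusted p = 0.094 against wildtype). Of 189 small nucleolar RNA genes 22 rose and 0 fell (median 0.37, estimated-correlation p = 0.0041), though their reads cannot be told from those of the hosts they lie in. Of 78 genes of cytosolic ribosomal proteins 8 rose, 0 fell and 77 were above 0 (median 0.28, estimated-correlation p = 0.15). Against Myc, 1 Snhg gene, 0 small nucleolar RNA genes and 0 ribosomal protein genes passed (medians 0.30, 0.23 and 0.15, estimated-correlation p = 0.019, 0.02 and 0.36, not adjusted). Between Myc and wildtype 0 genes of these families passed (medians 0.13, 0.15 and 0.13, estimated-correlation p = 0.017, 0.047 and 0.24, not adjusted). Of 5 measured genes of the Gsdmc family 4 fell against wildtype (median -1.89) and 4 against Myc (median -2.98), and 0 passed between Myc and wildtype (median 1.09). Of 354 solute carrier genes 19 rose and 7 fell against wildtype (median -0.06).

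In brackets after a count of called genes stands its range over fits with single libraries left out. Of 25 kidney development genes 4 fell (4 to 5) and 1 rose (0 to 6) in Grhl2KO_Myc against wildtype, with 5 lower and 1 higher when adjusted over the list alone (median -0.02, camera adjusted p = 0.21). Lhx1, a transcription factor gene of the early nephron, was 1.60-fold lower (54.0 ± 4.23 against 86.5 ± 8.59 CPM, adjusted p = 9.0e-04), and Hnf4a, a transcription factor gene of the proximal tubule, 1.56-fold lower (114 ± 13.7 against 178 ± 32.8 CPM, adjusted p = 0.012). Of 19 genes of the unfolded protein response 2 rose (1 to 4), with 5 higher when adjusted over the list alone (median 0.14, camera adjusted p = 0.0077, adjusted p = 0.41 with an estimated correlation), among them Asns, which makes asparagine (17.1 ± 1.62 against 9.42 ± 1.13 CPM, adjusted p = 0.0027). Of 18 p53-linked genes 2 rose (1 to 3) and 1 fell (0 to 1), with 3 higher and 1 lower when adjusted over the list alone (median 0.05, camera adjusted p = 0.40), and Aen was 1.37-fold higher (adjusted p = 0.0012). Of 12 urothelial genes 1 rose (1 to 2), also when adjusted over the list alone (median 0.52, camera adjusted p = 0.21): Krt15, a keratin gene, at 2.59 ± 0.449 against 0.797 ± 0.370 CPM (adjusted p = 0.0028). Of 16 glycolysis genes 1 rose (0 to 9), with 3 higher when adjusted over the list alone (median 0.15, camera adjusted p = 0.0017, adjusted p = 0.41 with an estimated correlation). Of 26 cytokine and complement genes 1 rose (0 to 2) and 1 fell (1 to 2), also when adjusted over the list alone (median 0.37 and -0.11 without Grhl2KO_Myc 2, camera adjusted p = 0.17), and Tnfaip2 was 1.36-fold lower (50.2 ± 7.88 against 68.1 ± 3.28 CPM, adjusted p = 0.012). Of 14 genes linked to epithelial-mesenchymal transition 2 fell (1 to 4), also when adjusted over the list alone (median -0.12, camera adjusted p = 0.081), among them the integrin gene Itgav (101 ± 8.99 against 129 ± 5.83 CPM, adjusted p = 0.0074).

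Smooth muscle genes (15, median -0.04 with a mean of 0.03, camera adjusted p = 0.65) had 1 lower gene and 17 lymphocyte genes had 1 lower (median -0.11, camera adjusted p = 0.47), with 1 higher and 2 lower in the latter when adjusted over the list alone and 1 lower in the former. Fatty acid oxidation (25 genes, median -0.03, camera adjusted p = 0.38) also had 1 lower gene either way, and male-biased kidney genes (10, median -0.31, camera adjusted p = 0.40) 1 higher and 1 lower either way. With single libraries left out, the lower genes numbered 1 among smooth muscle genes, 0 to 1 among lymphocyte and fatty acid oxidation genes and 0 to 4 among male-biased genes, of which 0 to 2 were higher. Of 9 adrenal genes 0 passed over all genes and 2 were higher when adjusted over the list alone (median 0.09, camera adjusted p = 0.41), with Chga at 22.9 CPM in Grhl2KO_Myc 2 against 0.16 to 0.76 CPM in the other libraries. No gene passed over all genes or over the list alone among 25 fibroblast and matrix genes (median -0.09, camera adjusted p = 0.023, kept in 6 of 9 fits with a library left out, adjusted p = 0.79 with an estimated correlation), 24 macrophage genes (0.07, 0.38), 11 neutrophil genes (-0.27, 0.19), 8 erythroid genes (-0.41, 0.018, kept in 7 of 9 fits, adjusted p = 0.50 with an estimated correlation) and 9 adipose genes (-1.31, 0.059), with the median and the camera adjusted p in brackets. The same held for oxidative phosphorylation (30 genes, -0.03, 0.45), cholesterol synthesis (20, -0.05, 0.38), the interferon response (24, -0.07 with a mean of 0.09, 0.40), immediate-early genes (18, 0.09, 0.41), female-biased kidney genes (9, -0.18, 0.48) and the 4 Y-linked genes (1.05, 0.38). With single libraries left out, the medians for kidney development (-0.09 to 0.04), smooth muscle (-0.13 to 0.14), macrophages (-0.08 to 0.14), the adrenal gland (-0.09 to 0.27), fatty acid oxidation (-0.20 to 0.04), oxidative phosphorylation (-0.06 to 0.01) and the interferon response (-0.37 to 0.09) took either sign.

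Between Myc and wildtype, lists with 0 genes called either way also passed camera for podocytes (median -0.14, -0.19 to -0.06 with single libraries left out, adjusted p = 0.00011, adjusted p = 0.23 with an estimated correlation), neutrophils (-0.69, -0.97 to -0.44, 0.00062, adjusted p = 0.46 with an estimated correlation), kidney development (-0.13, -0.16 to -0.06, 0.00062, adjusted p = 0.56 with an estimated correlation) and cholesterol synthesis (0.12, 0.08 to 0.17, 3.0e-04, adjusted p = 0.54 with an estimated correlation). The others with 0 called were immediate-early genes (-0.14, -0.23 to -0.09, 0.013, adjusted p = 0.56 with an estimated correlation), fibroblasts and matrix (-0.04, -0.08 to 0.01, 0.021, adjusted p = 0.63 with an estimated correlation), oxidative phosphorylation (0.04, 0.01 to 0.08, 0.039, adjusted p = 0.86 with an estimated correlation) and epithelial-mesenchymal transition (-0.07, -0.10 to -0.06, 0.039, adjusted p = 0.36 with an estimated correlation). The MYC-linked metabolism list, with 0 called over all genes and 1 higher when adjusted over the list alone, had a median of 0.12 (0.08 to 0.16, camera adjusted p = 2.8e-08, adjusted p = 0.43 with an estimated correlation). Between Grhl2KO_Myc and Myc, glycolysis genes with 0 called either way were all 16 above 0 (median 0.18, camera adjusted p = 0.00031, adjusted p = 0.33 with an estimated correlation), and 19 of 20 cholesterol synthesis genes, 0 called either way, were below 0 (median -0.16, camera adjusted p = 0.00037, adjusted p = 0.49 with an estimated correlation). Camera also called 8 lists with 0 genes called either way, given with the median, its range over fits with single libraries left out and the camera adjusted p. They were podocytes (-0.14, -0.20 to -0.10, 0.0024, adjusted p = 0.33 with an estimated correlation), the thick ascending limb (-0.15, -0.24 to -0.11, 0.015, adjusted p = 0.58 with an estimated correlation), cell cycle (-0.10, -0.16 to -0.05, 0.010, adjusted p = 0.70 with an estimated correlation) and oxidative phosphorylation (-0.06, -0.11 to -0.02, 0.015, adjusted p = 0.70 with an estimated correlation). Fatty acid oxidation (-0.13, -0.27 to -0.10, 0.010, adjusted p = 0.70 with an estimated correlation), the interferon response (0.29, 0.02 to 0.36, 0.032, adjusted p = 0.70 with an estimated correlation) and cytokines and complement (0.60, 0.09 to 0.75, 0.014, adjusted p = 0.70 with an estimated correlation) also had 0 called, the last pair with the lowest median without Grhl2KO_Myc 2. The same held for immediate-early genes (0.18, 0.16 to 0.23, 0.011, adjusted p = 0.58 with an estimated correlation). Distal convoluted tubule markers (-0.25, -0.36 to -0.18, 0.014, adjusted p = 0.45 with an estimated correlation) had 0 called over all genes and 5 lower and 2 higher over the list alone, and the unfolded protein response (0.14, 0.15 to 0.18, 0.0027, adjusted p = 0.33 with an estimated correlation) 0 over all genes and 4 higher and 1 lower over the list alone. Of p53-linked genes (0.09, 0.06 to 0.10, 0.028, adjusted p = 0.47 with an estimated correlation) 1 rose, Aen (0.39, SE 0.071, adjusted p = 0.027), and 2 were higher over the list alone.

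The ribosome biogenesis score differed between Grhl2KO_Myc and wildtype by 0.38 (SE 0.055). A difference in maturity between the groups could lower proximal tubule genes and raise growth genes, and the score still differed by 0.34 (SE 0.040) with the proximal tubule score as a covariate and by 0.35 (SE 0.035) without the 3 libraries lowest in it, which argues against maturity as the whole cause. With a sex term the difference was 0.37 (SE 0.059), which argues against sex as the whole cause. A wrong factor for a library would move all its genes alike, and relative to 9501 other genes of similar level the difference was 0.39 (SE 0.059), which argues against scaling as the whole cause. Against Myc the difference was 0.26 (SE 0.063), and 0.19 (SE 0.037) without the 3 libraries. The genotype, the age of the mice and differences between the crosses stay open and were not tested apart.

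The 13 genes on chromosome 4 that fell in Grhl2KO_Myc each match another of the 13 over at least 95% identity, so their fall may be that of few sources of reads counted at several genes. Loss of the whole interval stays open: the 15 genes not called against Myc had a median of -0.37 (SE 0.21) against -1.74, but called and other genes were told apart by the fall itself. A variant that segregates independently of the genotype stays open too: 0 of the 8 other libraries lay at or below the highest Grhl2KO_Myc library, which the choice of genes called lower in that group fixes. A difference in strain background fixed between the crosses stays open and was not tested. Counts equal to those of another gene in all 12 libraries occurred for 8 of the 23742 tested genes.

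Other splits of the same libraries were tested for as many calls. For the 200 genes called between Grhl2KO_Myc and Myc the real split gave the most (1 of 35 splits with as many, highest other 13). That share is the smallest that 35 splits can give and was not adjusted for the other split tests. It argues against chance without excluding it. For the 1584 between Grhl2KO_Myc and wildtype, 3 of 100 splits drawn gave as many, the real one among them. As other splits called 3071 and 1860 genes, that count alone does not exclude chance. The highest other split there called 3071 genes by placing wildtype 4 with the Grhl2KO_Myc libraries, which points to a structure of the samples, as wildtype 4, Grhl2KO_Myc 3 and Grhl2KO_Myc 4 lay together at 46.1, 34.4 and 42.1 on the first principal component. Chance could not be excluded for the 1 gene between Myc and wildtype (4 of 56 splits, highest other 6). For lists called by camera the real split between Grhl2KO_Myc and Myc gave the most (20 lists, 1 of 35 splits, highest other 19, median of the others 14.5). That margin is too narrow to exclude chance. Nor could chance be excluded between Myc and wildtype (14 lists, 16 of 56 splits, highest other 20) or Grhl2KO_Myc and wildtype (12 lists, 66 of 100 splits, highest other 22). With an estimated correlation 0 lists passed in each comparison, and the 20 lists became 17 without Myc 2 or Grhl2KO_Myc 2.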
